A study of Komagataella pastoris with 6 samples.

How the data were processed

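Messenger RNA was sequenced from 6 exponential-phase cultures of *Komagataella pastoris* (*Pichia pastoris*) in a basal salt medium with 0.5% methanol, 3 of the control strain HTX-33 and 3 of its derivative that overexpresses Ilv3. Libraries were made with a stranded, ligation-based mRNA kit. Per the labels, HISAT2, TopHat2 and DESeq2 were used by the authors; their versions, their order, the genome build and the annotation are not given in the sources used here. Genes carry PAS_ locus tags with a product description. None of the 5030 IDs was found in the reference gene table at hand (0 of 5030), so symbols were assigned from the descriptions and, for a few genes of methanol metabolism, from published locus tags. Product names are given for 2833 genes and missing for 2197.

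The deposited values are named FPKM, but every library sums to 1000000, which TPM does and FPKM does not. They were therefore treated as deposited TPM, though the sum alone does not show that they were scaled by transcript length. The deposited table also holds the authors' log2 fold change and p-value for each gene; whether the p-value is adjusted is not stated. Those columns were only compared with the fit described here. In them 2751 genes have p under 0.05, the sign of change is the same as here for 95.8% of 5025 genes, and r across genes of the log2 fold changes is 0.981. Scaled values keep no sequencing depth, so the depth per library is unknown, no counting interval was computed and no count-based test was run. Between 10 and 20 genes were listed at 0 TPM per library, and the 10 most abundant transcripts held 11.6% to 13.4% of the total.

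The test, the filter, the named-gene rule, the gene lists and all but 3 of the alternatives were chosen before the data were examined, when the values were assumed to be FPKM. Genes with a mean of at least 1 TPM over the 6 libraries were kept, which left 5025 and removed 5. Values were taken as log2(TPM + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05, two-sided, and a change of at least 2-fold means an absolute log2 fold change of at least 1. Named genes were ILV3, all measured genes of branched-chain amino acid synthesis, the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 10 TPM and no overlap between strains, up to 4 called members of each list with the largest changes, and AOX1, DAS1, DAS2, FLD1 and FDH1. This rule named 154 genes, of which the text gives a part.

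The 33 gene lists were matched to the descriptions before any value was examined. Of these, 32 with at least 5 measured members were tested with camera at its preset inter-gene correlation of 0.01, against all other genes, and adjusted over the 32 lists. Camera with an estimated correlation and fry, a rotation test of movement on balance that does not compare a list with other genes, were run beside it. Counts adjusted over the list alone come from the same limma p-values adjusted within the list.

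The procedure was tested on simulated data made from the library values, with noise drawn independently for each gene and library. It recovered 27, 39, 50 and 50 of 50 genes shifted by 0.3, 0.5, 1 and 2 on the log2 scale, and called 5 of 4820 unchanged genes. Without any simulated change limma called 0 of 5021 genes (272 at an unadjusted p under 0.05). With the proteasome list raised, camera called that list and 0 of 31 others (3 at an unadjusted p under 0.05). Independent noise leaves out correlation between genes, which was estimated at up to 0.49 in the lists of the real data (branched-chain synthesis). The simulation therefore cannot show how often camera at its preset correlation calls lists of correlated genes without a change.

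Same-numbered replicates of the strains were checked for shared deviations from their strain means. Their r across genes was 0.223, 0.126 and 0.209, each above the limit of 0.1, and for differently numbered pairs it ranged from -0.220 to 0.0412. Deviations from a strain mean cancel out within the strain, so higher values for same-numbered pairs push the others down. The range for differently numbered pairs is therefore not separate evidence. The labels do not say what the numbers share, so the fit stayed without a block, and the fit with the replicate number as a block is given where it changes the call of a named gene, beside that gene or, for 4 genes not named in the results, under the other settings. The other alternatives were pseudocounts of 0.1 and 5, no filter and a filter at a mean of 10 TPM, median-ratio scaling, quantile normalization, rescaling to 1000000, no mean-variance trend, robust empirical Bayes, each library left out in turn, and the branched-chain list without ILV3. The 3 alternatives chosen after the data were seen change list members: methanol utilisation without the genes matched by locus tag, chaperones with the membrane desiccation protein, and iron uptake with a pair of low-affinity iron transporters. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.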

Results

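Messenger RNA levels were measured in *Komagataella pastoris* (*Pichia pastoris*), a methylotrophic yeast that can use methanol as its carbon source. The samples were 3 libraries of the control strain HTX-33 and 3 libraries of a strain derived from it that overexpresses Ilv3 (the ILV3 strain), described by the series design as biological replicates. All 6 cultures grew in a basal salt medium with 0.5% methanol and were sampled in exponential phase. Expression was given for 5030 genes as values named FPKM. They sum to 1000000 in every library and were therefore treated as TPM, a length-scaled transcript share. The sequencing depth is unknown, so no counting interval can be given. Values are given as mean ± SD (SD, n = 3 libraries of a strain). Changes are log2 fold changes of the ILV3 strain over the control on the log2(TPM + 1) scale, which understates the change of weakly expressed genes.

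The comparison asks how the transcriptome of a strain engineered for branched-chain amino acid production differs from that of its control. ILV3 (PAS_chr1-4_0458), the gene of dihydroxyacid dehydratase, which makes the 2-oxoacid precursors of valine and isoleucine, rose from 86.5 ± 6.19 to 2626 ± 58.2 TPM, a 30.3-fold difference of means. Its log2 fold change was 4.91 (SE 0.05, adjusted p = 1.31e-10), the highest of all tested genes. In the control libraries ILV3 lay at 88.0, 79.8 and 91.9 TPM, and in the ILV3 libraries at 2564, 2680 and 2633 TPM. Native and introduced copies of this coding sequence are not told apart by the measure. Among the other genes, the sharpest falls included a highly expressed transcript for a membrane desiccation protein and a myo-inositol transporter, while most measured genes of ergosterol synthesis, chaperones, peroxisome biogenesis and methanol utilisation were called higher, by smaller amounts; the camera calls of these lists were lost with an estimated inter-gene correlation. Of 5025 genes tested with limma, 1113 were higher and 1365 were lower in the ILV3 strain at an adjusted p under 0.05, 2478 in all. Which direction held more genes depended on the scaling: with quantile normalization 54.1% of 2773 called genes were higher. Most of these changes were small. Their median absolute log2 fold change was 0.35, and 156 genes changed at least 2-fold, 41 of them higher and 115 lower. No product name is given for 90 of those 156 genes. In 2876 genes, 57.2% of those tested, the values of the strains did not overlap, against 10% by chance for 3 libraries against 3. Libraries of the same strain correlated across genes with r of 0.986 to 0.992, and libraries of different strains with r of 0.963 to 0.968; genes are not independent replicates. In the authors' deposited table, ILV3 has a log2 fold change of 4.94, and 2475 of the 2478 genes called with limma have the same sign of change there.

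The rest of the branched-chain amino acid pathway changed by far less than ILV3. Of 9 measured genes of the pathway, 4 rose, ILV3 among them, and 2 fell (5 higher and 2 lower when adjusted over the list alone, ILV3 included). BAT1, the mitochondrial branched-chain aminotransferase, rose from 77.9 ± 5.50 to 106 ± 5.98 TPM (log2 fold change 0.43, SE 0.07, adjusted p = 0.000549). LEU1 and LEU2, which act in the leucine branch, rose from 171 ± 4.97 to 215 ± 5.42 TPM and from 51.8 ± 1.30 to 65.8 ± 5.06 TPM, log2 fold changes of 0.33 and 0.34. ILV1, the threonine deaminase that opens isoleucine synthesis, fell from 36.8 ± 2.62 to 29.8 ± 0.919 TPM (log2 fold change -0.29). ILV2, the catalytic subunit of acetolactate synthase, fell from 162 ± 8.48 to 135.01 ± 2.26 TPM (log2 fold change -0.26, and -0.17 with quantile normalization). ILV5, the reductoisomerase acting just before ILV3, was at 1268 ± 20.4 TPM in the control and 1364 ± 51.6 TPM in the ILV3 strain, which did not pass the test (adjusted p = 0.0663). LEU4 was at 181 ± 8.19 and 175 ± 9.77 TPM (adjusted p = 0.493). ILV6, the regulatory subunit of acetolactate synthase, was listed near the floor at 2.06 ± 0.399 and 2.95 ± 0.526 TPM, and its adjusted p of 0.137 became 0.0492 with robust empirical Bayes and 0.0390 without a mean-variance trend, within a range of 0.0390 to 0.339 over its alternatives. As a whole the list did not pass the competitive gene set test, camera (adjusted p = 0.0914, and 0.367 without ILV3 itself). It passed upward with fry, a rotation test that does not compare a list with other genes (adjusted p = 0.000587). Fry was not run without ILV3, the overexpressed gene, so its result does not show a rise of the other members. Over the alternatives the adjusted p of the list ranged from 0.000587 to 0.741. The plot of the pathway's genes shows each library.

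**Figure D1:**
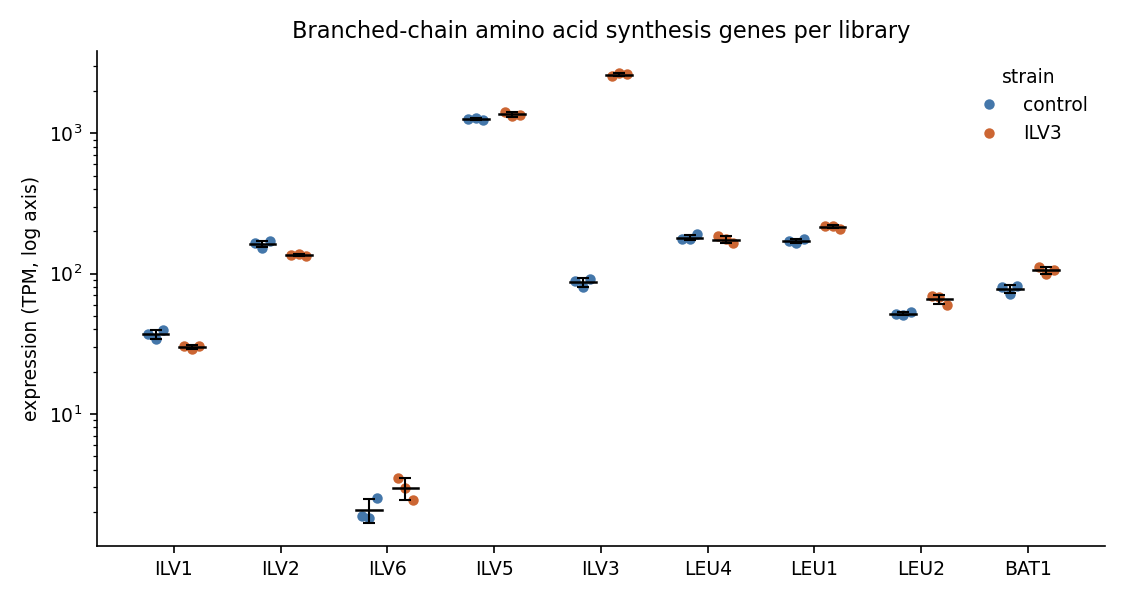
Expression of the 9 measured genes of branched-chain amino acid synthesis, in TPM on a log axis. Points are single libraries of the control and ILV3 strains, with the mean and SD over 3 libraries as black bars. ILV3 moves from about 86.5 to 2626 TPM, and the other 8 genes differ by at most 0.43 on the log2(TPM + 1) scale.

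The next lists are of routes with a step that takes up 2-oxoacids, though not all of their members act on them. Each list was tested alone, and the difference between them was not tested. In fusel alcohol and 2-oxoacid catabolism, through which yeasts turn 2-oxoacids into higher alcohols and acids, 7 of 11 genes fell and the other 4 did not pass the test (7 lower when adjusted over the list alone). A gene described as an NADPH-dependent medium-chain alcohol dehydrogenase (PAS_chr1-1_0357) fell from 13 ± 1.49 to 2.08 ± 0.849 TPM (log2 fold change -2.22, and -1.35 with a pseudocount of 5). A mitochondrial aldehyde dehydrogenase (PAS_chr4_0470) fell from 216 ± 6.24 to 115 ± 4.35 TPM. ARO10, a 2-oxoacid decarboxylase, fell from 160.2 ± 6.46 to 91.9 ± 17.3 TPM (log2 fold change -0.81, adjusted p = 0.000306). The list passed the set test downward (camera adjusted p = 0.0107), with adjusted p = 0.548 under an estimated inter-gene correlation. In pantothenate and coenzyme A synthesis, 5 of 7 genes rose, the same number as when adjusted over the list alone. Pantothenate kinase CAB1 rose from 121 ± 1.5 to 216 ± 6.30 TPM (log2 fold change 0.83). ECM31, the ketopantoate hydroxymethyltransferase that takes the valine precursor into pantothenate, rose from 28.5 ± 3.07 to 43.6 ± 1.52 TPM (log2 fold change 0.60). A polyamine oxidase resembling FMS1 (PAS_chr4_0823), an enzyme that in yeast supplies beta-alanine for pantothenate, rose from 22.5 ± 1.83 to 33.3 ± 1.95 TPM, and pantothenate synthase PAN6 rose from 166 ± 8.83 to 225 ± 2.45 TPM. This list passed upward (camera adjusted p = 0.00555; adjusted p = 0.27 with an estimated correlation).

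The 10 largest rises and the 10 largest falls among well expressed genes with separated values included 5 risers, ILV3 first, and 3 fallers with a product name. A glycosylphosphatidylinositol-anchored aspartic protease of the plasma membrane (PAS_chr3_0299) rose from 46.7 ± 3.71 to 214 ± 9.12 TPM (log2 fold change 2.17, SE 0.06, adjusted p = 3.17e-08). A subunit of the TRAPP vesicle-tethering complex (PAS_chr2-2_0180) rose from 42.9 ± 4.52 to 139 ± 6.70 TPM, and a peripheral protein of vacuole import and degradation vesicles (PAS_chr4_0047) rose from 69.9 ± 7.52 to 204 ± 17.2 TPM. A pair of myo-inositol transporters moved in opposite directions. The gene described as similar to the major yeast transporter (PAS_chr2-1_0489) rose from 58.9 ± 1.37 to 182 ± 14.8 TPM (log2 fold change 1.61), while the gene described as similar to the minor transporter (PAS_chr4_0828) fell from 1841 ± 32.7 to 331 ± 20.5 TPM (log2 fold change -2.47, SE 0.05, adjusted p = 3.82e-09). The plasma membrane protein that protects membranes from desiccation (PAS_chr4_0627) was among the most abundant transcripts of the control and fell from 13793 ± 389 to 761 ± 69.7 TPM, an 18.1-fold difference of means (log2 fold change -4.18, SE 0.07, adjusted p = 5.43e-10). A lectin-like protein similar to the flocculin Flo1p (PAS_chr1-4_0584) fell from 250.1 ± 19.9 to 38.8 ± 1.07 TPM (log2 fold change -2.66). The other 5 risers and 7 fallers have no product name. Among them, PAS_chr4_0151 rose from 139 ± 13.7 to 700.0 ± 45.1 TPM and PAS_chr2-2_0208 fell from 4340 ± 185 to 202.9 ± 16.3 TPM. For 1 unnamed riser and 1 unnamed faller, some libraries are listed at 0 TPM, and both calls were lost with robust empirical Bayes. The riser, PAS_chr4_0281, had an adjusted p of 0.0118, and 0.1 there (range 2.85e-06 to 0.1). The faller, PAS_chr1-4_0369, had an adjusted p of 0.0407, and 0.187 there (range 0.000496 to 0.187). Its call was also lost without control replicate 1, 2 or 3 (0.0591, 0.114 and 0.0771), without a mean-variance trend (0.0659), with median-ratio scaling (0.0597), with quantile normalization (0.0637) and with a pseudocount of 0.1 (0.0722), and without ILV3 replicate 2, the library at 0, its log2 fold change was -2.07 in place of -4.25.

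**Figure D2:**
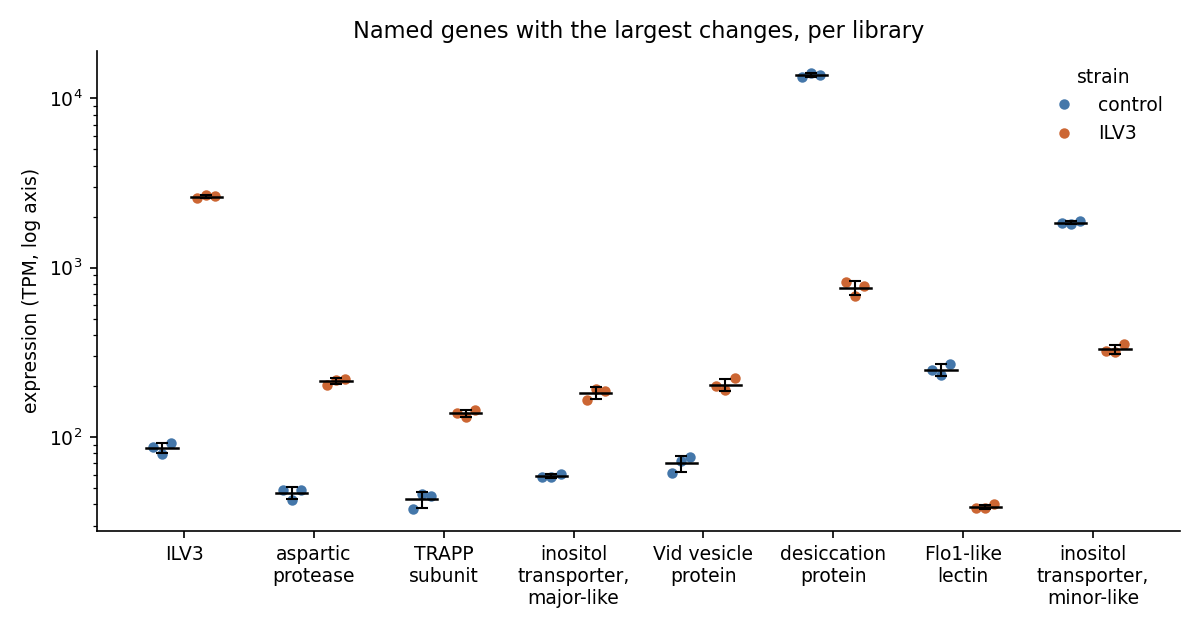
Expression of the genes with a product name among the 10 largest rises and 10 largest falls, in TPM on a log axis. Points are single libraries, black bars are the mean and SD over 3 libraries of a strain, and the values of the strains do not overlap for any gene shown. The desiccation protein drops from about 13793 to 761 TPM.

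Methanol utilisation genes were already among the most abundant transcripts, and most rose slightly. Of 18 measured genes, 13 rose and 2 fell (13 higher and 2 lower when adjusted over the list alone). The log2 fold changes of the 18 genes ranged from -0.44 to 0.89. AOX1, the alcohol oxidase that oxidises methanol, was the highest transcript of every library and rose from 21686 ± 704 to 30219 ± 1998 TPM (log2 fold change 0.48, SE 0.06, adjusted p = 0.0002). Quantile normalization gives every top-ranked gene the same value, so AOX1 has no fold change there. SHB17, a sedoheptulose bisphosphatase of the xylulose monophosphate cycle matched by its locus tag alone, rose from 2393 ± 115 to 4443 ± 188 TPM (log2 fold change 0.89). MIT1, a transcription factor of methanol genes also matched by locus tag, rose from 927 ± 49.8 to 1477 ± 27.6 TPM, and the aldolase FBA1-2 rose from 2252 ± 51.1 to 3358 ± 39.1 TPM. FDH1, formate dehydrogenase, rose from 11600 ± 139 to 13142 ± 245 TPM (log2 fold change 0.18, and 0.35 with quantile normalization). DAS1 and DAS2, the dihydroxyacetone synthases, rose from 6896 ± 277 to 7811 ± 240.0 TPM and from 9444 ± 342 to 10345 ± 152.4 TPM, log2 fold changes of 0.18 and 0.13 (0.09 and 0.28 with quantile normalization). The DAS2 call was weak. Its adjusted p of 0.0401 became 0.121 with the replicate number as a block and 0.0560 without a mean-variance trend, and lay above 0.05 without any 1 of the 6 libraries (0.0560 to 0.105), within a range of 8.03e-05 to 0.121 over all its alternatives. DAS1 lost its call with quantile normalization (adjusted p = 0.230, range 0.00649 to 0.230). FLD1, which oxidises the glutathione adduct of formaldehyde, fell from 6968 ± 58.1 to 6425 ± 103 TPM (log2 fold change -0.12, adjusted p = 0.0378), a call lost with the block (adjusted p = 0.137), with median-ratio scaling (0.219), without a mean-variance trend (0.0571) and when any 1 library other than control replicate 2 was left out (0.0589 to 0.111; range over all alternatives 0.00754 to 0.219). AOX1 and AOX2, like DAS1 and DAS2, are near-identical copies, and how reads were shared within each pair is not given in the sources used here. The list passed upward (camera adjusted p = 0.00314; adjusted p = 0.27 with an estimated correlation; 0.0201 without its 4 members matched by locus tag, an alternative chosen after the data were seen; range 0.000532 to 0.27). In peroxisome biogenesis, 13 of 18 genes rose and 3 fell, with the same numbers when adjusted over the list alone. PEX4, a ubiquitin-conjugating enzyme of receptor recycling, rose from 231 ± 8.79 to 349.6 ± 3.18 TPM (log2 fold change 0.60). The adenine nucleotide transporter PMP47 rose from 202 ± 4.61 to 299.6 ± 12.8 TPM, PEX19 rose from 156 ± 4.34 to 226 ± 3.45 TPM, and PEX8 rose from 188 ± 12.8 to 246 ± 7.97 TPM. Camera called this list upward (adjusted p = 0.00144; adjusted p = 0.548 with an estimated correlation).

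In a competitive set test, ergosterol synthesis was the list with the lowest camera p. Of its 21 measured genes, 19 rose and the other 2, ERG4 and ERG8, did not pass the test (20 higher when adjusted over the list alone). Farnesyl pyrophosphate synthetase ERG20 rose from 344 ± 2.69 to 722 ± 19.4 TPM (log2 fold change 1.07, SE 0.04, adjusted p = 7.56e-08). ERG24, the C-14 sterol reductase, rose from 26.7 ± 3.06 to 51.3 ± 1.66 TPM, ERG10, the acetoacetyl-CoA thiolase, rose from 276 ± 7.80 to 512 ± 16.8 TPM, and ERG3, the C-5 sterol desaturase, rose from 909.8 ± 73.7 to 1622 ± 39.7 TPM. The median log2 fold change of the list was 0.36 (camera adjusted p = 1.1e-08; adjusted p = 0.308 with an estimated correlation). Among cytosolic and mitochondrial chaperones, 9 of 12 genes rose and 1 fell (10 higher and 2 lower when adjusted over the list alone). HSP104, a disaggregase, rose from 1923 ± 106 to 3618 ± 221 TPM (log2 fold change 0.91). A pair of genes described as the Hsp90 co-chaperone Aha1 rose from 738 ± 25.6 to 1270 ± 72.1 TPM and from 304 ± 11.7 to 474 ± 18.3 TPM, and the mitochondrial chaperone HSP78 rose from 747 ± 46.1 to 1205 ± 58.9 TPM. The member that fell was HSF1, the heat shock transcription factor, which was named after its value was seen (from 44.5 ± 2.26 to 28.3 ± 2.54 TPM). The list passed upward (camera adjusted p = 0.000493; adjusted p = 0.473 with an estimated correlation). The desiccation protein named above carries the description of yeast Hsp12. HSP12 was among the planned members of this list, but the gene was not matched to it. With it added after the data were seen, the camera adjusted p was 0.00546, still upward (range 0.000121 to 0.473).

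Genes of energy metabolism that rose did so by small amounts. In oxidative phosphorylation 11 of 22 genes rose and the other 11 did not pass the test (12 higher when adjusted over the list alone). An F1F0 ATP synthase subunit (PAS_chr2-1_0751) rose from 1386 ± 167 to 1886 ± 133 TPM, and the cytochrome c oxidase subunits COX12 and COX8 rose from 1822 ± 118 to 2362 ± 209 TPM and from 1548 ± 93.0 to 1944 ± 113 TPM. Camera gave an adjusted p of 0.00209, and the adjusted p = 0.27 with an estimated correlation. In glycolysis and gluconeogenesis 9 of 16 genes rose (10 higher and 2 lower when adjusted over the list alone). A phosphoglycerate mutase (PAS_chr3_0826) rose from 1219 ± 64.3 to 1861 ± 31.4 TPM, and hexokinase-2 rose from 465 ± 13.9 to 679 ± 10.2 TPM (camera adjusted p = 0.00831; adjusted p = 0.27 with an estimated correlation). Mitochondrial ribosomal proteins also passed upward, with 18 of 61 genes higher and 4 lower (16 higher and 3 lower when adjusted over the list alone). The small-subunit protein RSM7 rose from 51.9 ± 3.27 to 69.4 ± 1.19 TPM and the large-subunit protein RML2 rose from 101 ± 4.14 to 134.7 ± 3.13 TPM (camera adjusted p = 0.0172; adjusted p = 0.548 with an estimated correlation). The tricarboxylic acid cycle list, with 9 genes higher and 3 lower of 23 (9 higher and 3 lower when adjusted over the list alone), did not pass (camera adjusted p = 0.0574), but did with fry (0.0122), with median-ratio scaling (0.0464), with quantile normalization (0.0242) and without control replicate 2 (0.0443), within a range of 0.0122 to 0.687. Malate synthase (PAS_chr4_0191) fell from 269 ± 5.74 to 157 ± 19.4 TPM, and mitochondrial malate dehydrogenase (PAS_chr2-1_0238) rose from 1131 ± 20.2 to 1495 ± 21.8 TPM. The pentose phosphate list had 1 gene higher and 2 lower of 6 (1 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.599, but 0.0147 downward with fry; range 0.0147 to 0.836), with the transketolase TKL1 falling from 147 ± 9.15 to 86.5 ± 2.97 TPM and the ribose-5-phosphate isomerase RKI1-1 rising from 169 ± 0.943 to 229.9 ± 2.08 TPM.

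Besides fusel alcohol catabolism, camera called a pair of lists downward at its preset correlation, and both calls were lost with an estimated correlation (adjusted p of 0.741 for ribosome biogenesis and 0.548 for slow growth). In ribosome biogenesis 36 of 101 genes fell and 4 rose (4 higher and 35 lower when adjusted over the list alone). A component of 66S pre-ribosomal particles (PAS_chr3_0094) fell from 57.3 ± 2.55 to 33.4 ± 1.99 TPM (log2 fold change -0.76), the 60S export protein NMD3 fell from 82.9 ± 0.679 to 50.5 ± 2.19 TPM, and a subunit of RNase MRP (PAS_chr1-4_0517) fell from 30.4 ± 0.740 to 18.3 ± 0.573 TPM. The list's median log2 fold change was -0.14 (camera adjusted p = 0.00555). Cytosolic ribosomal protein genes did not pass as a list (camera adjusted p = 0.323, but 0.0359 downward with quantile normalization; range 0.0359 to 0.833), with 4 higher and 24 lower of 84 (4 higher and 20 lower when adjusted over the list alone). The 40S protein S29 rose from 3173 ± 366 to 4332 ± 209.6 TPM. The 60S protein L9 fell from 412 ± 71.4 to 324 ± 21.2 TPM, a call lost when any 1 library other than control replicate 2 was left out (adjusted p of 0.0531 to 0.12), and with robust empirical Bayes (0.137), no mean-variance trend (0.0650) or quantile normalization (0.0997), within a range of 0.000470 to 0.137. In central and energy-store metabolism of slow growth, 11 of 18 genes fell and 3 rose (4 higher and 11 lower when adjusted over the list alone). Those that fell furthest are enzymes of peroxisomal fatty acid oxidation and of trehalose synthesis. The 3-ketoacyl-CoA thiolase POT1 fell from 252 ± 14 to 79.3 ± 8.48 TPM (log2 fold change -1.66), the acyl-CoA oxidase POX1 fell from 153 ± 8.0 to 77.8 ± 7.91 TPM, the multifunctional enzyme FOX2 (PAS_chr2-1_0776) fell from 216 ± 14.3 to 119 ± 7.43 TPM, and TSL1, a subunit of trehalose-6-phosphate synthase, fell from 232 ± 12.7 to 106 ± 2.67 TPM. Camera gave an adjusted p of 0.0241 for this list, 0.0611 without control replicate 2, and the adjusted p = 0.548 with an estimated correlation (range 0.000717 to 0.548).

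**Figure D3:**
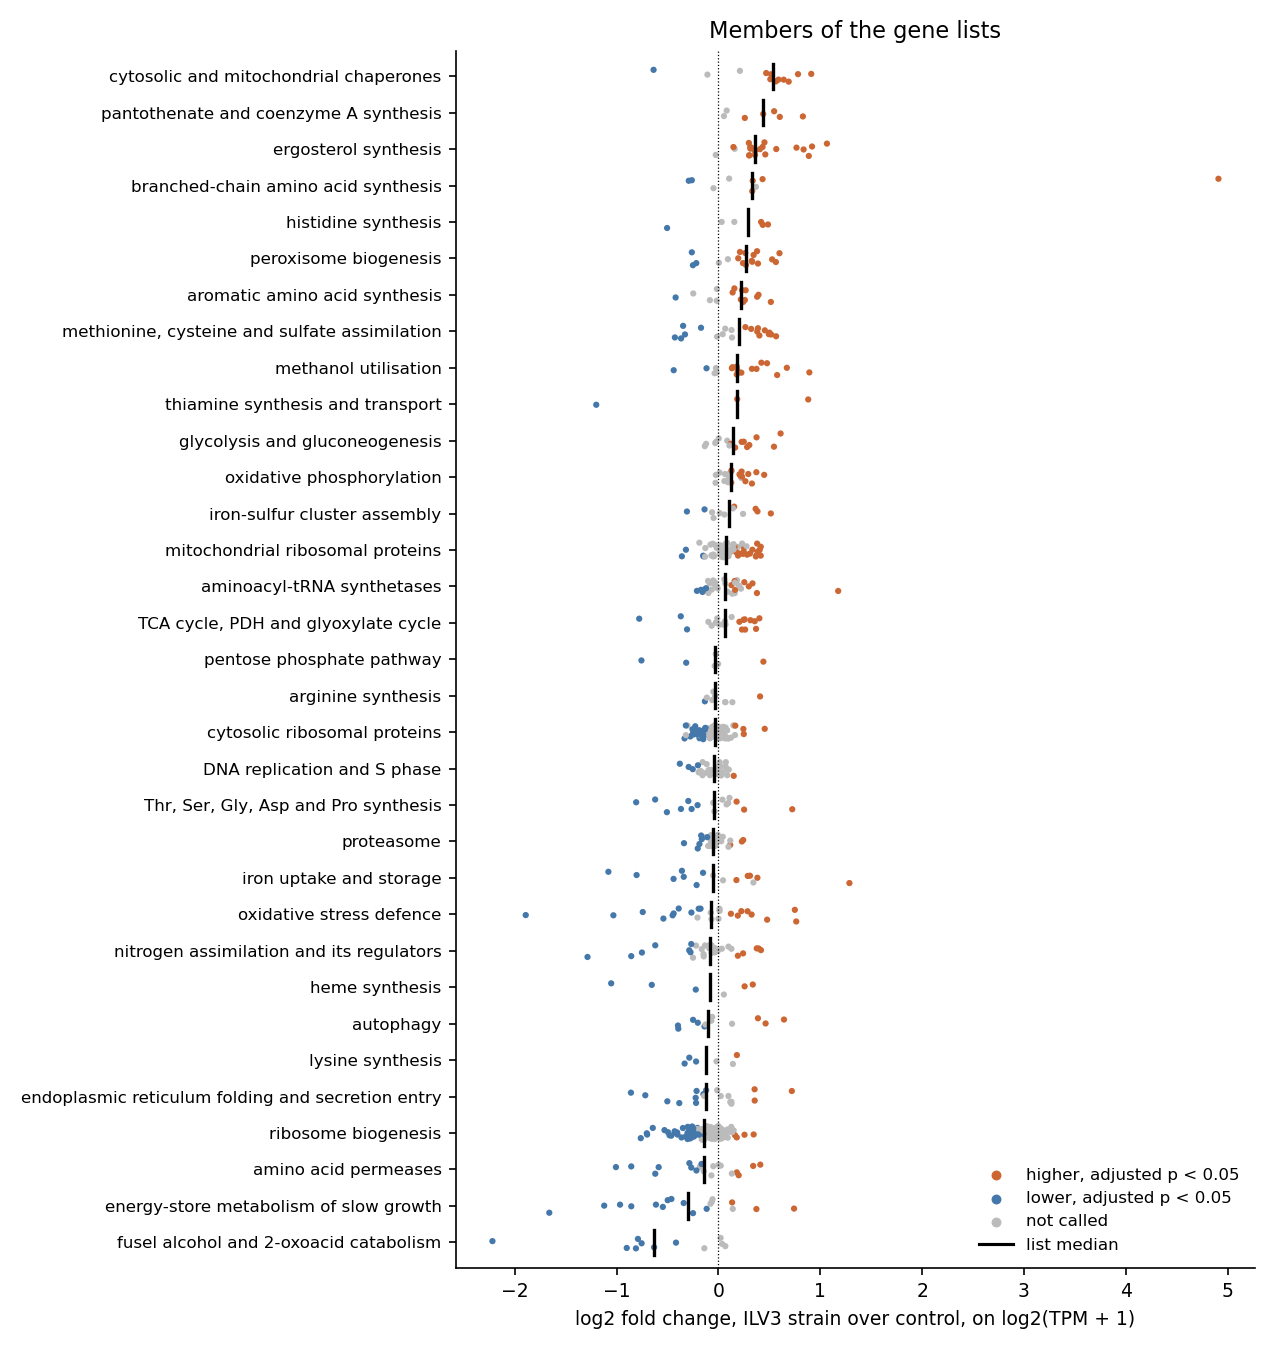
Log2 fold changes of the members of 33 gene lists, ILV3 strain over control, on the log2(TPM + 1) scale, with 1 point per gene. Orange points rose and blue points fell at an adjusted p under 0.05, grey points did not pass, and a black bar marks each list's median. ILV3 stands apart at 4.91, and 19 of 21 ergosterol genes lie among the orange points.

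Other amino acid pathways changed in part. Aromatic amino acid synthesis had 10 of 15 genes higher and 1 lower, with the same numbers when adjusted over the list alone. Prephenate dehydratase PHA2 rose from 26.8 ± 0.820 to 38.7 ± 1.90 TPM, and TRP1 fell from 36.8 ± 1.66 to 27.2 ± 0.770 TPM (camera adjusted p = 0.0288, 0.0721 without ILV3 replicate 1; adjusted p = 0.548 with an estimated correlation; range 0.00717 to 0.548). Methionine, cysteine and sulfate assimilation had 10 of 20 genes higher and 5 lower (12 higher and 5 lower when adjusted over the list alone). Cystathionine beta-lyase STR3 rose from 21.3 ± 2.68 to 31.9 ± 1.07 TPM, and a methylenetetrahydrofolate reductase (PAS_chr2-2_0145) rose from 37.6 ± 4.19 to 54 ± 0.312 TPM. This list's camera adjusted p of 0.0356 became 0.0530 without a mean-variance trend and 0.0524 without ILV3 replicate 1, and the adjusted p = 0.741 with an estimated correlation (range 0.0178 to 0.741). Camera made no call for histidine synthesis (3 higher and 1 lower of 6; camera adjusted p = 0.238, but 0.0147 upward with fry; range 0.0147 to 0.548), where HIS6 fell from 267 ± 5.88 to 188 ± 11.6 TPM and HIS3 rose from 339.6 ± 19.7 to 476 ± 14.2 TPM, nor for lysine synthesis (1 higher and 3 lower of 6; adjusted p = 0.52, but 0.0227 downward with fry; range 0.0227 to 0.833), where the homocitrate synthase LYS21 fell from 1075 ± 18.6 to 854 ± 27.7 TPM and the saccharopine dehydrogenase LYS9 fell from 216 ± 2.96 to 177.01 ± 4.96 TPM. Both keep these numbers when adjusted over the list alone. Arginine synthesis had 1 gene higher and 1 lower of 9 (1 higher and 0 lower when adjusted over the list alone); its median log2 fold change was -0.03 while its mean and its test pointed upward (camera adjusted p = 0.69), and CPA1, a carbamoyl phosphate synthetase subunit, rose from 76.3 ± 2.10 to 102 ± 4.66 TPM. ARG4, argininosuccinate lyase, fell from 144 ± 4.78 to 131 ± 1.95 TPM. Its adjusted p of 0.0304 became 0.0879 with the replicate number as a block, 0.559 with quantile normalization and 0.0506 without a mean-variance trend. It lay above 0.05 without any 1 library other than control replicate 2 (0.0537 to 0.119; range over all alternatives 0.0130 to 0.559). Of 16 genes of threonine, serine, glycine, aspartate and proline synthesis, 3 rose and 7 fell, the same as when adjusted over the list alone (camera adjusted p = 0.599, but 0.00966 downward with fry; range 0.00966 to 0.833). The proline enzymes PRO1 and PRO2 fell from 98.2 ± 1.08 to 55.6 ± 0.301 TPM and from 269 ± 4.73 to 175 ± 5.46 TPM, and aspartate kinase HOM3 rose from 99.3 ± 7.98 to 164 ± 4.34 TPM. Nitrogen assimilation and its regulators had 5 higher and 7 lower of 30 (5 higher and 6 lower when adjusted over the list alone; camera adjusted p = 0.423, but 0.00385 downward with fry; range 0.00385 to 0.747). Succinate semialdehyde dehydrogenase UGA2 fell from 162 ± 5.28 to 65.7 ± 1.16 TPM (log2 fold change -1.29), and a general amino acid permease (PAS_chr1-1_0030) fell from 485 ± 45.5 to 268 ± 33.2 TPM. Among all 19 amino acid permeases 4 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.323, but 0.0039 downward with fry; range 0.0039 to 0.741), with the lysine permease LYP1 falling from 117 ± 3.62 to 57.7 ± 4.92 TPM and a proline permease (PAS_chr2-1_0129) falling from 23.9 ± 0.408 to 15.2 ± 0.855 TPM.

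Dihydroxyacid dehydratase carries an iron-sulfur cluster, and single genes of iron metabolism moved in both directions. For scale, 49.3% of all tested genes were called, and a link of these genes to the cluster was not tested. Iron-sulfur cluster assembly had 4 of 12 genes higher and 2 lower (5 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.303, but 0.0024 upward with fry; range 0.0024 to 0.548), among them ERV1, a sulfhydryl oxidase, which rose from 34.7 ± 3.75 to 49.9 ± 2.34 TPM, and a protein of mitochondrial iron metabolism (PAS_chr1-4_0109), which rose from 197 ± 6.38 to 257 ± 3.42 TPM. Iron uptake and storage had 5 of 15 higher and 7 lower, the same as when adjusted over the list alone (camera adjusted p = 0.651). A ferrioxamine B transporter (PAS_chr3_0662) fell from 172 ± 7.04 to 80.9 ± 5.10 TPM (log2 fold change -1.08), and a siderophore transporter of the ARN family (PAS_chr3_0315) rose from 1.14 ± 0.248 to 4.21 ± 0.206 TPM (log2 fold change 1.29, and 0.58 with a pseudocount of 5). In heme synthesis 2 of 6 genes rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.599, but 0.000426 downward with fry; range 0.000426 to 0.839). HEM12, uroporphyrinogen decarboxylase, fell from 149 ± 6.87 to 71.5 ± 2.06 TPM (log2 fold change -1.05), the ferrochelatase HEM15 fell from 96.7 ± 1.67 to 61.1 ± 0.811 TPM, and HEM13 rose from 419 ± 32.9 to 528 ± 9.69 TPM. Thiamine genes, too few for a set test, are given singly. The thiazole synthase THI4 rose from 915 ± 45.8 to 1685 ± 33.7 TPM (log2 fold change 0.88). THI5 fell from 78.5 ± 39.3 to 32.4 ± 10.6 TPM, a call lost with robust empirical Bayes (adjusted p = 0.111, range 3.80e-05 to 0.111), and THI80 rose from 68.8 ± 4.43 to 78.2 ± 1.58 TPM, a call lost with the replicate number as a block (adjusted p = 0.0507) and without control replicate 1, ILV3 replicate 1 or ILV3 replicate 2 (0.0509 to 0.0743; range over all alternatives 0.00231 to 0.0743).

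The remaining lists did not pass camera. Oxidative stress defence had 8 of 24 genes higher and 10 lower, also when adjusted over the list alone (camera adjusted p = 0.599, but 0.000587 downward with fry; range 0.000587 to 0.839). The glutathione S-transferase GTT1 fell from 1309 ± 11.6 to 352 ± 14.3 TPM (log2 fold change -1.89) and the peroxiredoxin AHP1 fell from 4976 ± 44.3 to 2434 ± 39.2 TPM, while the thioredoxin peroxidase TSA1 rose from 322 ± 12.8 to 547 ± 22.1 TPM and a mitochondrial peroxiredoxin (PAS_chr1-1_0433) rose from 1472 ± 89.1 to 2477 ± 169 TPM. Endoplasmic reticulum folding and secretion entry had 3 higher and 9 lower of 19, also when adjusted over the list alone (camera adjusted p = 0.62), and SBH1, a subunit of the Sec61 translocon, fell from 214 ± 28.6 to 117 ± 9.54 TPM, while a DnaJ homologue (PAS_chr2-2_0015) rose from 31.6 ± 1.13 to 52.7 ± 2.99 TPM. Autophagy had 3 higher and 5 lower of 12, also when adjusted over the list alone (camera adjusted p = 0.944); an ATG18-like gene rose from 53.0 ± 2.14 to 83.4 ± 2.96 TPM, and ATG27 rose from 152.4 ± 7.31 to 210.3 ± 8.39 TPM. Camera leaned down and fry up for this list, neither passing. Aminoacyl-tRNA synthetases had 8 higher and 5 lower of 31 (7 higher and 5 lower when adjusted over the list alone; camera adjusted p = 0.3), with the mitochondrial threonyl-tRNA synthetase rising from 5.91 ± 0.797 to 14.6 ± 1.41 TPM and the mitochondrial glutamyl-tRNA synthetase (PAS_chr1-1_0241) rising from 19.2 ± 0.827 to 25.2 ± 1.72 TPM. The proteasome had 3 higher and 6 lower of 31 (2 higher and 5 lower when adjusted over the list alone; camera adjusted p = 0.599), and an ATPase of the 19S particle (PAS_chr4_0731) fell from 235 ± 7.60 to 186 ± 8.53 TPM, while a non-ATPase subunit of the 26S particle (PAS_chr1-1_0299) rose from 208 ± 16.7 to 246 ± 13.2 TPM. DNA replication had 1 higher and 4 lower of 30 genes (0 and 4 when adjusted over the list alone; camera adjusted p = 0.566), with the ribonucleotide reductase subunit RNR2 falling from 149 ± 12.4 to 114 ± 2.04 TPM and the large subunit RNR1 (PAS_chr1-1_0282) falling from 163 ± 15.1 to 133 ± 4.42 TPM.

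In all, camera called 13 of 32 lists with its preset inter-gene correlation, 10 upward and 3 downward. With an estimated correlation camera called 0 lists (5 at an unadjusted p under 0.05), and fry called 24, among them all 13. Other groupings of the same 6 libraries gave between 1 and 9 lists by the preset test while calling at most 1 gene. Those groupings mix libraries of both strains on each side, so they are not free of a strain difference.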

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

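The number of gene lists past the threshold depended on the set test. It was 13 with camera at its preset correlation and 0 with camera at an estimated correlation (5 at an unadjusted p under 0.05). With fry, which does not compare a list with other genes, it was 24. The cause of these differences was not tested. The estimated correlation lay below the preset 0.01 for oxidative phosphorylation (0.0079), glycolysis and gluconeogenesis (-0.023), and pantothenate and coenzyme A synthesis (-0.091). Their adjusted p still rose to 0.27, which argues against a higher correlation as the source of the loss in these lists. Every other list called at the preset correlation had an estimate above 0.01. Since this setting raised the adjusted p even without a higher correlation, the loss of those calls cannot be put down to correlation alone. With the other settings the number of lists was 12 to 15, and leaving out each library in turn gave 11 to 13. Of the 13 lists, 10 kept the call under each of 16 settings of the fit; the exceptions are aromatic amino acids, slow growth, and methionine, cysteine and sulfate.

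The counts of genes stayed within 1.5 times their value. Over the other settings 2211 to 2773 genes changed, 983 to 1499 were higher, 1228 to 1382 were lower and 128 to 161 changed at least 2-fold. Leaving out each library gave 2120 to 2689 changed, 937 to 1060 higher, 1120 to 1629 lower and at most 165 at least 2-fold. The ILV3 log2 fold change lay between 4.85 and 4.95 in both. The share of called genes that were higher was 44.9%, 49% with median-ratio scaling, 54.1% with quantile normalization and 39.4% without control replicate 2, so which direction holds more genes depends on the scaling; these settings moved the median of all genes by under 0.05. Of 2478 called genes, 2402 were also called with median-ratio scaling and 2307 with quantile normalization, none in the opposite direction.

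With the replicate number as a block, 2211 genes changed, 44.5% of them higher, and 13 lists passed. Of 191 results 183 stayed on their side of the threshold. Besides the calls lost with the block that are given with their genes, it ended those of LYS2 (adjusted p = 0.0754), the DNA primase subunit PAS_chr4_0323 (0.0505), and the mitochondrial asparaginyl- and leucyl-tRNA synthetases PAS_chr1-1_0392 (0.101) and PAS_chr1-4_0534 (0.0606). Among these 191 results it changed no other call, and 2173 of all 2478 called genes were also called with the block.

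Of 154 named genes, 137 stayed on the same side of the threshold under each of 16 settings. A result called in neither fit was counted as unchanged even where its sign differed. AOX1 has a log2 fold change of 0 with quantile normalization by construction, since it is the top gene of every library. Rescaling to 1000000 changes nothing, because the libraries already sum to it. The count-based alternatives were not run, since the values are scaled and are not read counts, and the depth that limits weakly expressed genes is unknown.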

Other observations

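Apart from the counts of splits, the comparisons in this part were chosen after the results were seen, though some of them use list tests planned before. A set of 13 genes described as peroxisomal fatty acid oxidation was put together after their values were seen, and 4 of them are in the slow-growth list. Of these, 9 fell, 2 rose and 2 did not pass limma. The search was narrowed from a wider one over descriptions, in which 12 of 19 genes fell, 4 rose and 3 did not pass. Next to POT1, POX1 and FOX2, a peroxisomal 2,4-dienoyl-CoA reductase (PAS_chr2-2_0019) fell from 777 ± 28.1 to 371 ± 4.66 TPM (SD, n = 3; log2 fold change -1.06, lower in 3 of 3 libraries). The subunits of a peroxisomal ATP-binding cassette transporter (PAS_chr2-2_0272 and PAS_chr3_0822) fell from 22.4 ± 1.47 to 11.1 ± 0.536 TPM and from 44.3 ± 0.684 to 23.3 ± 1.43 TPM. The genes that rose were an acyl-CoA thioesterase (PAS_chr2-1_0545), from 32.5 ± 1.00 to 40.9 ± 1.68 TPM, and a further dienoyl-CoA reductase (PAS_chr4_0338), from 49.4 ± 0.813 to 60 ± 1.06 TPM.

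Further genes were picked out after their values were seen. Proteins described as ammonia exporters fell from 351 ± 37.2 to 117 ± 6.34 TPM (PAS_chr1-1_0378) and from 413 ± 29.5 to 154 ± 18.8 TPM (PAS_chr1-1_0158), while another (PAS_chr1-1_0417) rose from 1437 ± 62.4 to 2766 ± 142 TPM. Arginase (PAS_chr4_0684) rose from 109.9 ± 2.34 to 255 ± 3.44 TPM. A pair of genes described as low-affinity iron transporters (PAS_chr2-2_0009 and PAS_chr4_0008), missed when the iron list was matched, rose from 175 ± 4.47 to 379 ± 25.4 TPM and from 5.96 ± 0.282 to 11.1 ± 0.637 TPM; with them the list had a camera adjusted p of 0.735 (range 0.0723 to 0.852). This alternative was first run with only the more strongly changed gene of the pair and was then corrected to hold both. Searches of set tests over words in the descriptions, of neighbouring locus tags and of medians per chromosome were also looked at and are not reported.

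Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 2478 genes changed, 1113 higher, 1365 lower and 156 at least 2-fold, and the highest other split gave 1 for each of these counts, with either side of a split taken as the ILV3 strain; 1 of the 10 splits gave as many, the real one. For gene lists the real split gave 13 and the highest other 9. Of the 4 splits that part all 3 same-numbered pairs, 1 is the real one. The other 3 called 0 genes each with limma (50, 221 and 43 at an unadjusted p under 0.05) and 2, 9 and 7 lists with camera's preset test. Every split but the real one mixes libraries of both strains on each side. Part of the strain difference therefore stays in the comparison, and the rest widens the spread within a side. These splits cannot show how many genes or lists would be called without a strain difference.

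Of the tested genes 49.3% were called. A shift of all other transcripts by a few abundant ones could do this, but it would move most called genes one way, and the smaller direction held 44.9% of them. What stays open is any difference between the cultures that follows the strain, such as harvest density, which is not given in the sources used here.

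The fall of the membrane desiccation protein transcript may have several sources. Loss of the gene is argued against by 683 TPM in the lowest ILV3 library. A fall shared by chaperone transcripts is argued against by 9 of 12 chaperone list members called higher, with HSF1 lower. These 12 leave out the desiccation protein itself, which has the description of Hsp12, a planned member. With it added, the list still passed upward (camera adjusted p = 0.00546). Other stress transcripts are not covered by that list, and oxidative stress defence had 8 of 24 genes higher and 10 lower. A fall of other stress transcripts along with the desiccation protein was not tested. Faster growth of the ILV3 strain at harvest cannot be told apart, because the tests of the ribosome biogenesis list differ: it was lower with camera (adjusted p = 0.00555) and fry (0.0147), but the adjusted p was 0.741 with an estimated correlation. The slow-growth list went the other way, as faster growth would have it, with 11 of 18 genes lower (camera adjusted p = 0.0241, 0.0611 without control replicate 2; fry 0.000717), and its adjusted p was 0.548 with an estimated correlation. The slow-growth list shares POT1, POX1 and FOX2 with the fatty acid oxidation genes above, and POT1 was its largest fall (log2 fold change -1.66). The direction of that list and the fall of those genes are therefore not separate observations. A response to Ilv3 itself stays open and was not tested.

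For the fall of fatty acid oxidation transcripts, fewer peroxisomes in the ILV3 strain could be a source. Of 18 peroxisome biogenesis genes 13 rose and 3 fell, which argues against a shared fall of these transcripts. Peroxisome number was not measured, so whether it differed cannot be told from transcript levels. For scaling of the samples as a source, 9 members were called lower under both median-ratio scaling and quantile normalization. These settings moved the median log2 fold change of all genes by only 0.023 and 0.041, while the 9 members changed by -0.41 to -1.66. The kept calls were therefore near certain beforehand and are no evidence of their own. A shift of all genes of that size is too small to give the fall. A regulatory difference between the strains stays open as a hypothesis and was not tested.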
